A study of Mus musculus with 20 samples.

How the data were processed

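RNA was measured by sequencing in macrophages sorted from visceral adipose tissue (VAT) and spleen of male mice as cells positive for F4/80 and CD11b, which are surface proteins of mouse macrophages and other myeloid cells. The mice were 3 or 24 months old and were wild type or lacked Nlrp3, the sensor protein of an inflammasome, a complex that activates caspase-1. Per the labels, the libraries were strand-specific and made from poly-A RNA, and CASAVA 1.8.2, TopHat, Partek and DESeq2 were used with the mm10 genome. The labels do not say what each program did, how reads were counted, on which strand, or which genes were removed.

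Each of the 3 deposited tables holds 1 signal per gene and library, which is a normalised gene read count. The wild-type table holds the 13 wild-type libraries, the VAT table the 11 VAT libraries and the spleen table the 9 spleen libraries, so the wild-type libraries stand in 2 tables each. The tables were normalised separately, and no comparison was made across them except where stated. In each library the values above 1 were whole multiples of a single step, which is the inverse of its size factor, and the lowest value was exactly 1 in every library. At least 99.769% of the values up to 20000 reads were whole within 0.05 read. A direct search for the step starting at the lowest value found it in 20 of the 33 columns, and in the others only once the entries at 1 were left out. Whole reads were recovered from these steps, with each value of 1 taken as 0 reads. The VAT table differed from the wild-type table in 62 of 91476 shared entries, in 53 genes, and 60 of these lay within 10% of the 0.2-trimmed mean of the gene. The spleen table differed from the wild-type table in 0 of 77904 shared entries within 6 reads. Entries of the libraries without Nlrp3 could not be checked in this way, since they stand in 1 table each.

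The recovered reads per library came to 27.3 to 36.8 M (mega) in the wild-type table, 27.7 to 37.5 M in the VAT table and 24.1 to 32.8 M in the spleen table. A count of 3 reads, taken as the most that a count of 0 allows, corresponds to 2.33 to 3.85 normalised counts. Such floors cover counting error only, because reads without molecular identifiers are not independent molecules. Where a gene stood at 1 in every library of a group, its fold is given against the mean 3-read floor of that group. This is a nominal lower bound, written as "at least". In libraries whose step was under 1, a value of 1 can stand for 1 read as well as for 0. The mean of the other group was taken as it stood, so the bound leaves out the spread between libraries. Entries at 1 numbered 453 to 1347 per library in the wild-type table, 102 to 309 in the VAT table and 325 to 694 in the spleen table. Pairs of libraries of 1 group had Spearman correlations of 0.9562 to 0.9831 across genes, which are not independent replicates. Their squared differences, as chi-square per degree of freedom, were 33.36 to 208.7 times those of counting error.

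The comparisons, tests, gene lists, alternatives and the rule for the genes named were fixed before the data were examined. Genes with a mean of at least 10 over the libraries of a table were tested, which left 13702 of 13954 genes in the wild-type table, 13090 of 13129 in the VAT table and 13053 of 13169 in the spleen table. Values were taken as log2 with a pseudocount of 1, and each table was fitted once with a mean per group in limma 3.58.1 with a trend (R 4.3.3). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Age was compared in the wild-type table in VAT and in spleen, tissue at 24 months and the tissue by age interaction in the wild-type table, and genotype at 24 months in the VAT and spleen tables. No table holds all 4 groups of the tissue by genotype interaction. For it, the VAT and spleen tables were joined on recovered reads and rescaled by median of ratios, a step added after seeing the data. The labels give no identity of animals, so libraries were treated as independent. It is not known whether VAT and spleen libraries came from the same mice, or whether young and old mice came from the same colony, so an age effect here is a difference between the age groups.

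Lists of 37 gene groups covered catecholamine breakdown, synthesis and receptors, inflammasome, cytokine, interferon, lysosome, lipid, iron, metabolism, cell cycle, antigen presentation and macrophage state genes, and markers of other cell types. Each list with at least 3 tested members was tested with camera in limma with its preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Counts of members over all genes tested stand beside counts adjusted over the list alone. In the lists of the genotype comparisons Nlrp3 itself was left out.

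The genes named are Nlrp3 in every sample, up to 8 genes with the largest rise and 8 with the largest fall per comparison among those called with groups apart, up to 2 called members of each list, and Maoa, Gdf3, Il1b and Casp1 whatever their result. Some genes that the rule selects are not reported here. Predicted genes and clone names were left out of the largest changes. After the results were seen, room in the text was given first to named genes whose call held under every alternative, and in the tissue comparison only the first member of each list was taken. Genes named outside this rule are marked as chosen after their values were seen. Positions are from the GENCODE annotation of the mm10 assembly (GRCm38), where 175 of 177 symbols looked up matched 1 gene.

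Alternatives fixed in advance were a pseudocount of 0.5 or 10, no filter or a minimum of 50, median-of-ratios rescaling, quantile normalisation, robust limma, only the groups compared, another table with both groups, edgeR 4.0.16 on recovered reads, the replicate number as a block, and leaving out each library in turn. DESeq2 1.42.0 on recovered reads, and the VAT table with its differing entries set back to the reads of the wild-type table, were added after seeing the data. Where leaving out a library left 1 library in a group, that library was assumed to vary like the other groups. The tests were checked on 1 simulated data set per comparison with 100 genes changed 2-fold and 100 changed 4-fold. Of these, limma recovered 27 and 64 for age in VAT, 21 and 56 for age in spleen, 44 and 76 for genotype in VAT, 45 and 78 for genotype in spleen, 34 and 68 for tissue, 2 and 45 for tissue by age, and 14 and 72 for tissue by genotype. The false calls came to 3 to 8 with limma and 25 to 42 with DESeq2. All values per sample in the deposited tables were used.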

Results

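The series held 20 libraries of sorted F4/80 and CD11b positive macrophages in 6 groups of male mice. From VAT there were 3 libraries of 3-month wild-type mice, 4 of 24-month wild-type mice and 4 of 24-month Nlrp3-null mice. From spleen there were 2, 4 and 3 libraries of the same ages and genotypes. The series title names macrophage catecholamine breakdown driven by the inflammasome in ageing, which the age and genotype comparisons address. The deposited values stand in 3 tables, of the wild-type, VAT and spleen libraries. Recovered reads in M (mega) per library in the wild-type table came to 27.7 to 36.6 for 3-month VAT and 32.8 to 36.8 for 24-month VAT. In spleen they came to 30.2 to 31.8 at 3 months and 27.3 to 32.8 at 24 months. The Nlrp3-null libraries held 30.4 to 37.5 M reads in VAT (the VAT table) and 24.1 to 31.4 M in spleen (the spleen table). Principal components of each table were taken over its genes with the largest variance only. The first component of the wild-type table held 86.1% of the variance of these genes and separated the tissues, and the second held 3.14%. On the first component of the spleen table, 3-month spleen replicate 1 lay at -83.18 and replicate 2 at -16.54. On the second component of the VAT table, 24-month wild-type VAT replicate 1 lay at -63.21, and the other VAT libraries between -7.19 and 17.03. Values below are normalised read counts, given as mean ± SD with the number of libraries (n).

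Did the libraries carry the genotype of their label? Nlrp3 (chromosome 11, 59541568 to 59566956 in mm10) encodes the sensor of the inflammasome that the null mice lack. In VAT at 24 months it stood at 3508 ± 654 (n = 4) in wild type and 56.8 ± 95.8 (n = 4) in null libraries, with 200.4 in null replicate 4 and 6.15 to 10.51 in the other null libraries. In spleen it stood at 481 ± 134 (n = 4) in wild type and 1.87 ± 1.51 (n = 3) in null libraries, where the values were 1, 3.61 and 1. Nlrp3 fell by 7.39 on the log2 scale in VAT (adjusted p = 0.000864) and by 7.47 in spleen (adjusted p = 1.77e-05), with every null library below every wild-type library. As null libraries stand near the floor, the size of this log2 depends on the pseudocount and the tool, from -8.48 to -5.93 in VAT and from -8.87 to -5.34 in spleen over the alternatives, and it was -8.48 in VAT without null replicate 4. No library contradicted its genotype label.

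**Figure D1:**
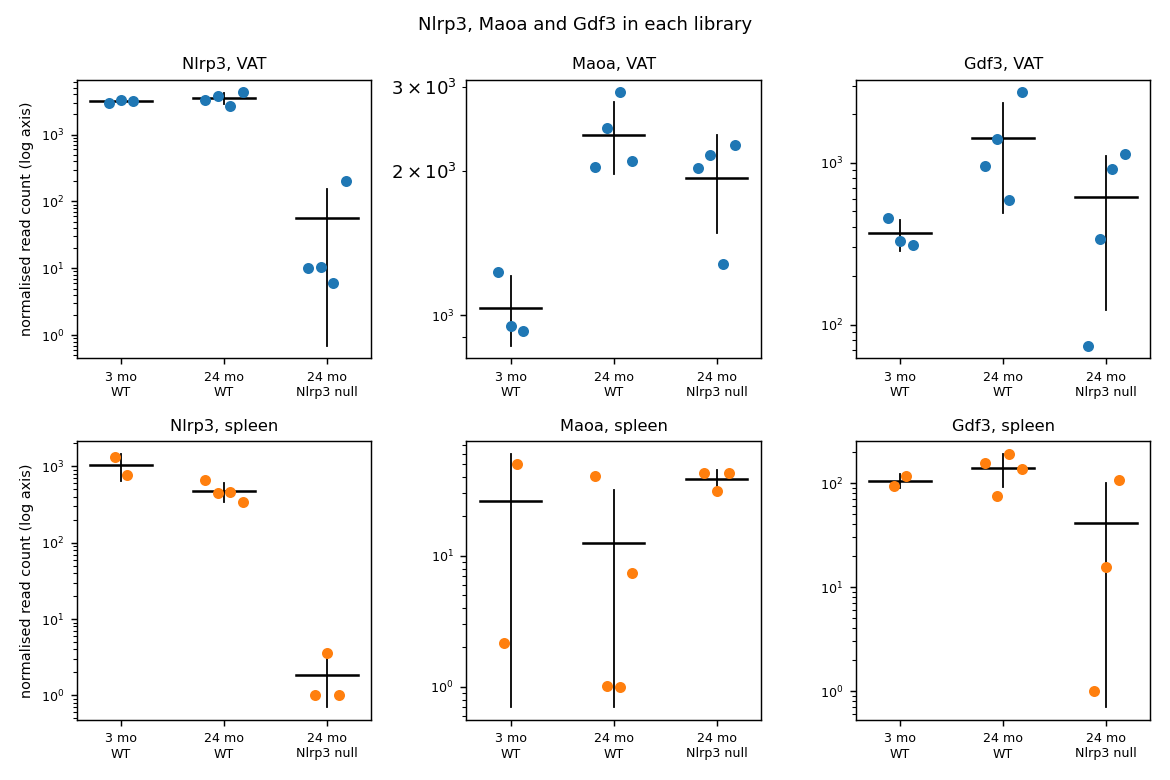
Normalised read counts (log scale) of Nlrp3, Maoa and Gdf3 in each library, from the VAT table for VAT and the spleen table for spleen. Points are libraries, bars are group means and lines are ± SD, with line ends that would reach 0 or below drawn to the bottom of the axis. In VAT, Nlrp3-null replicate 4 stands at 200.4 normalised counts of Nlrp3.

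What changed with age in VAT macrophages? Of the B cell markers 5 of 11 rose and of the plasma cell markers 2 of 5, and the calls of both lists were lost (adjusted p = 0.193 and adjusted p = 0.202 with an estimated correlation). Cd79a (chromosome 7, 24897381 to 24902197), a chain of the B cell receptor, rose from 99.3 ± 13.7 (n = 3) at 3 months to 1180 ± 1030 (n = 4) at 24 months. Jchain, which joins secreted antibodies, rose from 5187 ± 3259 to 34010 ± 11790. Of the MHC class II genes 6 of 13 fell, in a list whose call was lost (adjusted p = 0.193 with an estimated correlation), among them H2-DMb2 (chromosome 17, 34143307 to 34151555) from 3303 ± 454 to 789 ± 198 and H2-DMa from 42510 ± 10050 to 18570 ± 3714, both of which encode chains that help to load peptides. Gdf15 (chromosome 8, 70629393 to 70632456), a stress-induced cytokine, rose from 3681 ± 621 to 15520 ± 4871. Ccr2, the receptor that brings monocytes into tissue, fell from 25760 ± 3876 to 10140 ± 3045.

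The log2 fold changes in VAT were 3.24 for Cd79a (adjusted p = 0.000402), 2.86 for Jchain (0.000507), -2.09 for H2-DMb2 (9.51e-05), -1.19 for H2-DMa (0.000911), 2.04 for Gdf15 (0.0015) and -1.39 for Ccr2 (0.00102). Without 24-month VAT replicate 4, which held 2719 counts of Cd79a, the log2 fold change of Cd79a was 2.73. Faim3, a receptor of IgM, rose from 16 ± 13.1 to 300.3 ± 330.2, with 795 in 24-month replicate 4. Its log2 of 4.30 was 3.66 without that library, 3.12 without 3-month replicate 1 and 4.96 without 3-month replicate 3. Eaf2, a transcription elongation factor, rose from 12.89 ± 20.53 to 126 ± 33. Its log2 of 4.53 was 3.84, 5.93 and 3.81 without 3-month replicates 1, 2 and 3. Nr1h4, the bile acid receptor, was at least 15.5-fold higher at 24 months. Hhip, an inhibitor of hedgehog signals, was at least 16.1-fold lower, and Tenm2 at least 15.2-fold lower. C3, the central complement protein, rose from 3482 ± 345 to 10500 ± 3181 (adjusted p = 0.000636). Usp18, an interferon-induced protease, rose from 841 ± 91.8 to 1630 ± 247 (0.003). Fn1, which encodes fibronectin, fell from 63990 ± 11630 to 21260 ± 8610. The endothelial and leukocyte adhesion gene Pecam1 fell from 583 ± 154 to 198 ± 47.8. The NK cell receptor gene Klrk1 fell from 1780 ± 239 to 352 ± 123. The eosinophil ribonuclease gene Ear2 fell from 18620 ± 3936 to 3514 ± 1491. The beta globin genes Hbb-b2 and Hbb-bt had identical values, so their reads were not separable and they stand as 1 measurement, which fell from 574 ± 45.9 to 106 ± 98.1. Counts of genes and of erythroid markers hold it as 2 members.

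Of the genes named in the title's theme, Maoa (chromosome X, 16619698 to 16687818), which encodes monoamine oxidase A of catecholamine breakdown, stood at 1078 ± 186 (n = 3) at 3 months and 2549 ± 449 (n = 4) at 24 months in VAT, higher in 4 of 4 libraries (log2 1.24, SE 0.94, adjusted p = 0.496). That fit shared its estimate of spread with the spleen libraries, where the residual SD of Maoa on the log2 scale was 2.24 against 0.244 in VAT. With the VAT libraries alone the adjusted p was 0.00189, and in the VAT table it was 0.0032, within a range of 0.00189 to 0.727 over all alternatives. Gdf3 (chromosome 6, 122605403 to 122610087), a growth differentiation factor, rose from 382 ± 85.3 to 1512 ± 981 (log2 1.78, adjusted p = 0.0285). This call was lost in the VAT table (0.148), with the replicate number as a block (0.0683) and without 3-month VAT replicate 1 (0.0589), 2 (0.0971) or 3 (0.143) and 24-month VAT replicate 2 (0.0831) or 4 (0.0698). Its adjusted p ranged from 0.000236 to 0.148 over the alternatives. Casp1 (chromosome 9, 5298517 to 5307265), which encodes the protease of the inflammasome, stood at 2324 ± 204 and 3642 ± 276 (log2 0.65, adjusted p = 0.0602). It was called with the VAT libraries alone (0.0113), in the VAT table (0.00657), with a pseudocount of 10 (0.0496) and by DESeq2 (0.027), within a range of 0.00657 to 0.179. Il1b (chromosome 2, 129364570 to 129371139), which encodes the cytokine IL-1β, stood at 35470 ± 1102 and 29910 ± 6109 (adjusted p = 0.549), and Nlrp3 at 3284 ± 180.3 and 3751 ± 684 (adjusted p = 0.726).

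Among the gene lists in VAT, 18 of 36 were called for age, 10 upward and 8 downward, and none of these calls held with an estimated correlation (0 lists) while fry called 11. Of the catecholamine breakdown list 2 of 15 members rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.00674, and adjusted p = 0.193 with an estimated correlation). These were Akr1a1 and Aldh2, general aldehyde-processing enzymes whose calls were lost without several single libraries, the highest adjusted p being 0.143 and 0.204 without 3-month VAT replicate 3. Type I interferon genes rose in 6 of 24 and fell in 0 (12 and 1 adjusted over the list alone, 1.77e-05, and adjusted p = 0.202 with an estimated correlation). Lysosome genes rose in 7 of 23 and fell in 0 (9 and 0 over the list alone, 1.4e-06, and adjusted p = 0.202 with an estimated correlation). Lipid-associated macrophage genes rose in 4 of 19 and fell in 0 (7 and 1, 0.00376, and adjusted p = 0.556 with an estimated correlation). Among them Trem2 (chromosome 17, 48346401 to 48354147), a lipid receptor, rose from 3065 ± 415 to 9139 ± 4801 (adjusted p = 0.0219), a call lost without 3-month VAT replicate 1 (0.0533), 2 (0.0844) or 3 (0.111), with a range of 0.000103 to 0.111 over the alternatives. MHC class II genes fell in 6 of 13 and rose in 0 (8 and 1, 2.28e-07, and adjusted p = 0.193 with an estimated correlation). Complement and coagulation genes rose in 4 of 19 and fell in 1 (8 and 2, 0.00803, and adjusted p = 0.315 with an estimated correlation).

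The other macrophage lists in VAT gave, with counts of members that rose and fell and, in brackets, those adjusted over the list alone, 3 and 0 of 14 growth differentiation factor and TGF-β genes (3 and 0, camera adjusted p = 0.0415, and adjusted p = 0.193 with an estimated correlation) and 1 and 0 of 21 resident macrophage genes (1 and 0, 0.0499, and adjusted p = 0.707 with an estimated correlation). Iron and haem genes gave 2 and 0 of 17 (4 and 0, 0.03, and adjusted p = 0.538 with an estimated correlation). Cell cycle genes gave 0 and 1 of 25 (0 and 5, 8.79e-05, and adjusted p = 0.538 with an estimated correlation) and glycolysis genes 0 and 3 of 20 (1 and 5, 0.0469, and adjusted p = 0.595 with an estimated correlation). The lists that camera did not call were inflammasome, 0 and 1 of 18 (1 and 1, 0.554), NF-κB cytokines, 1 and 0 of 23 (2 and 0, 0.219), senescence, 3 and 1 of 13 (3 and 1, 0.554), oxidative phosphorylation, 0 and 1 of 24 (0 and 0, 0.321), and cholesterol handling, 1 and 0 of 24 (1 and 0, 0.439). Immediate early genes gave 0 and 1 of 22 (0 and 1, 0.582), pan-macrophage markers 1 and 0 of 11 (3 and 3, 0.237) and large peritoneal macrophage markers 0 and 1 of 11 (3 and 3, 0.877). Catecholamine synthesis genes gave 0 and 0 of 4 (0 and 0, 0.754), and the 2 measured adrenergic receptor genes were too few for a list test, with 0 called. The test and the mean of the senescence list were upward with a median of -0.0888, and large peritoneal markers had a downward test and a median of -0.2325 with a mean of 0.1389.

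Markers of other cell types moved with age in VAT beside the macrophage genes above. B cell markers rose in 5 of 11 and fell in 0 (7 and 0 adjusted over the list alone, 2.86e-05, and adjusted p = 0.193 with an estimated correlation). Plasma cell markers rose in 2 of 5 and fell in 0 (3 and 0, 0.00556, and adjusted p = 0.202 with an estimated correlation). NK cell markers fell in 2 of 12 and rose in 0 (6 and 1, 0.00302, and adjusted p = 0.193 with an estimated correlation). Endothelial markers fell in 4 of 11 (5 and 0, 2.9e-05, and adjusted p = 0.193 with an estimated correlation). Erythroid markers fell in 7 of 15 (7 and 1, 0.00119, and adjusted p = 0.375 with an estimated correlation). Dendritic cell markers fell in 1 of 12 (3 and 0, 0.027, and adjusted p = 0.193 with an estimated correlation). Nerve and glia markers fell in 0 of 5 (1 and 0, 0.0181, and adjusted p = 0.193 with an estimated correlation). Lists not called were T cell, 0 rose and 1 of 14 fell (0 and 1, 0.62), monocyte, 0 and 1 of 10 (1 and 3, 0.121), neutrophil, 0 and 0 of 14 (0 and 0, 0.442), eosinophil, 1 and 2 of 10 (1 and 2, 0.347), and mast cell and basophil, 0 and 0 of 10 (0 and 0, 0.768). Adipocyte markers gave 0 and 0 of 10 (0 and 0, 0.554), fibroblast markers 1 and 1 of 13 (4 and 2, 0.256), mesothelial markers 0 and 0 of 7 (0 and 0, 0.226) and megakaryocyte markers 1 and 0 of 10 (1 and 0, 0.419).

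**Figure D2:**
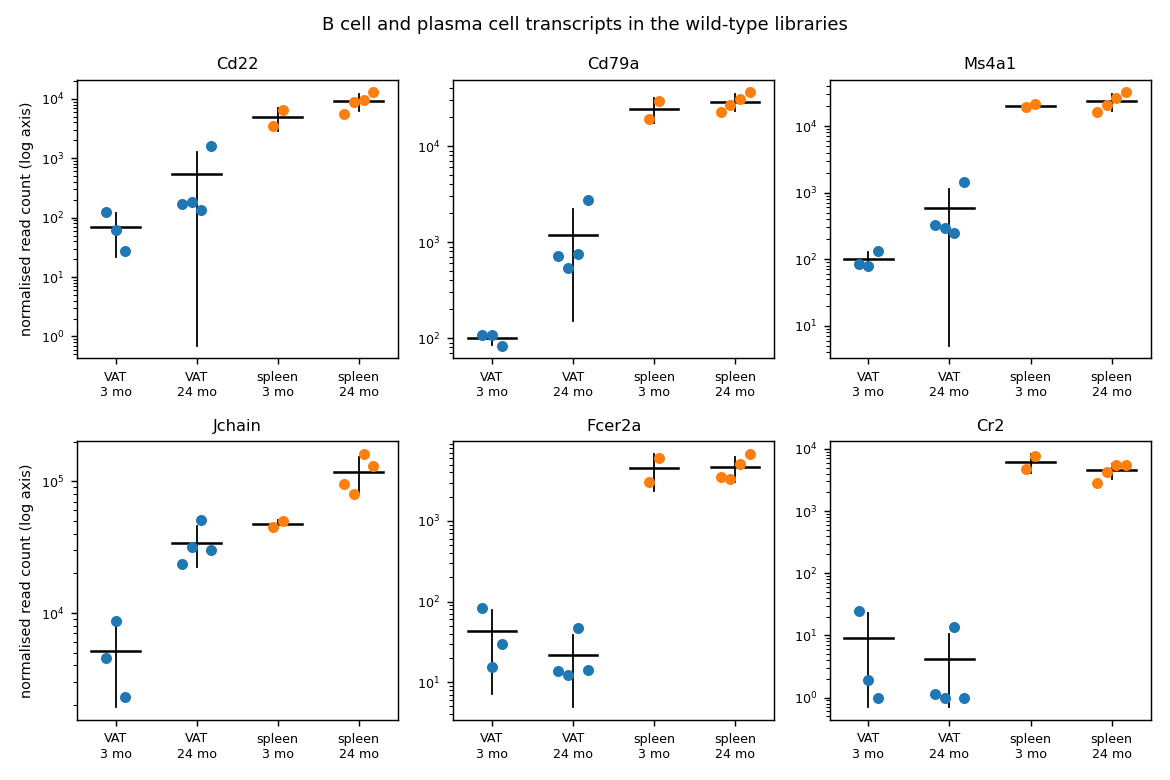
Normalised read counts (log scale) of the B cell and plasma cell genes Cd22, Cd79a, Ms4a1, Jchain, Fcer2a and Cr2 in each wild-type library of the wild-type table. Points are libraries, bars are group means and lines are ± SD, with line ends that would reach 0 or below drawn to the bottom of the axis. Cd79a in VAT rises from a mean of 99.3 at 3 months to 1180 at 24 months, and VAT replicate 4 at 24 months holds 2719.

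With limma, 740 of 13702 genes were called for age in VAT, 306 higher and 434 lower, against 2827 at an unadjusted p under 0.05, and edgeR called 642. Over all genes tested the groups did not overlap in 22.85%, where chance alone would keep a gene's groups apart in 5.71% of cases. Of the genes named and called, which were chosen for their difference, 58 of 61 did not overlap. The balance of higher and lower genes turned with the VAT libraries alone (592 higher and 567 lower). The count was 1159 with the VAT libraries alone, 1225 in the VAT table, 1172 with DESeq2, 216 without 3-month replicate 3, 388 without replicate 2, 417 without replicate 1 and 464 without 24-month replicate 2. Of the 61 genes named and called, 23 stayed called under every alternative.

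What changed with age in spleen macrophages? The comparison had 2 libraries at 3 months and 4 at 24 months. These libraries also held transcripts of other cells, such as the B cell gene Ms4a1 (mean 23670 at 24 months). Whether a difference arose within macrophages or from the mix of sorted cells was not tested. Rsad2, an interferon-induced antiviral gene, fell from 2719 ± 164 (n = 2) to 765 ± 285 (n = 4). C5ar1 (chromosome 7, 16246743 to 16259540), the receptor of complement fragment C5a, fell from 23360 ± 5160 to 8982 ± 1002. Itgam, which encodes CD11b itself, fell from 9093 ± 434 to 4399 ± 766. Tyrobp, a signalling adaptor of myeloid receptors, fell from 61720 ± 4527 to 29560 ± 5810. Sdc1, a plasma cell surface gene, rose from 267 ± 76.5 to 1927 ± 646. Aldh1a1, a retinal-oxidising enzyme, rose from 13.1 ± 12.7 to 214 ± 150.

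The log2 fold changes in spleen were -1.90 for Rsad2 (adjusted p = 0.00245), -1.37 for C5ar1 (0.00313), -1.06 for Itgam (0.0056), -1.08 for Tyrobp (0.00496), 2.81 for Sdc1 (0.000242) and 4.08 for Aldh1a1 (0.00264). Aldh1a1 had log2 2.99 without 3-month replicate 1 and 5.17 without replicate 2. Fosl2, an AP-1 transcription factor, fell from 3632 ± 46.1 to 1089 ± 196. Trabd2b rose from 1.01 ± 0.0122 to 196 ± 71.7. Chst1, a sulfotransferase, rose from 7.11 ± 8.64 to 330 ± 21.8, and Tspan7 from 1.01 ± 0.0122 to 147 ± 102. The log2 of Chst1 was 5.95, with 4.54 without 3-month replicate 1 and 7.37 without replicate 2. Mmp23 was at least 38.1-fold higher, and Tubb3, a tubulin of neurons, at least 25.8-fold higher at 24 months.

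Il1b fell in spleen from 20720 ± 380.5 to 9716 ± 3310 (log2 -1.16, adjusted p = 0.0192), a call lost without 3-month replicate 1 (0.108) or 2 (0.0629) and with quantile normalisation (0.0502), with a range of 0.00124 to 0.108. Nlrp3 fell from 979 ± 394 to 441 ± 124 (log2 -1.13, adjusted p = 0.024), a call lost without 3-month replicate 1 (log2 -0.71, 0.269), with the spleen groups alone (0.0881), with the replicate number as a block (0.0619) and in the spleen table (0.358), within a range of 0.00172 to 0.358. Maoa stood at 23.9 ± 31 and 11.6 ± 17.5 (adjusted p = 0.642), and its direction turned without 3-month replicate 2 (log2 0.96). Gdf3 stood at 98 ± 13.5 and 128 ± 44.9 (0.782), and Casp1 at 1994 ± 848 and 2577 ± 436 (0.272), with a log2 fold change of -0.03 without 3-month replicate 2.

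Camera called 8 of 36 lists in spleen, 2 upward and 6 downward, 0 with an estimated correlation, and fry called 5. Type I interferon genes fell in 8 of 24 and rose in 0 (10 and 0 adjusted over the list alone, camera adjusted p = 7.12e-05, and adjusted p = 0.491 with an estimated correlation). MHC class II genes rose in 4 of 13 and fell in 0 (8 and 0, 2.84e-05, and adjusted p = 0.297 with an estimated correlation), among them H2-Aa from 86380 ± 1181 to 142000 ± 2336, a call lost without 3-month replicate 1 (adjusted p = 0.0939). Neutrophil markers fell in 5 of 14 and rose in 0 (7 and 0, 2.33e-05, and adjusted p = 0.297 with an estimated correlation), among them S100a9 from 159000 ± 14700 to 55150 ± 15390, a call lost without 3-month replicate 1 (adjusted p = 0.0861) or 2 (0.0638). Plasma cell markers rose in 3 of 5 and fell in 0 (4 and 0, 8.71e-05, and adjusted p = 0.297 with an estimated correlation). Immediate early genes fell in 3 of 22 (9 fell and 1 rose over the list alone, 0.00347, and adjusted p = 0.634 with an estimated correlation). Glycolysis genes fell in 2 of 20 (7 and 0, 0.00961, and adjusted p = 0.645 with an estimated correlation). Monocyte markers fell in 1 of 10 (3 and 0, 0.0119, and adjusted p = 0.491 with an estimated correlation) and erythroid markers in 0 of 15 (0 and 0, 0.0326, and adjusted p = 0.673 with an estimated correlation). The inflammasome list was not called, with 4 of 18 lower and called (4 fell and 2 rose over the list alone, 0.241), nor was catecholamine breakdown, with 1 of 15 higher and called (1 and 0, 0.608). Test and mean differed in sign for growth differentiation factor, resident macrophage and large peritoneal genes (mean 0.0521, 0.0062 and 0.0102, tests downward), and the oxidative phosphorylation list had a median of -0.0375 and a mean of 0.0356.

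With limma, 850 genes were called for age in spleen, 384 higher and 466 lower, against 3013 at an unadjusted p under 0.05, and edgeR called 654. Over all genes tested the groups did not overlap in 27.3%, where chance would keep groups of 2 and 4 apart in 13.3% of cases. Of the genes named and called, which were chosen for their difference, 51 of 52 did not overlap. The balance of higher and lower genes turned with quantile normalisation (431 higher and 337 lower), without 3-month replicate 1 (128 and 52) and without replicate 2 (576 and 372). Without 3-month replicate 1 the count was 180, without 24-month replicate 3 it was 498, with the spleen groups alone it was 546 and with DESeq2 1435. Of the 52 genes named and called, 12 stayed called under every alternative.

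Did age act differently in VAT and spleen macrophages? The tissue by age interaction tests the difference of the 2 age effects, given here as VAT minus spleen. It does not tell a change within macrophages from a change in the mix of sorted cells. The MHC class II gene H2-Eb1, which encodes a chain that presents peptides, went from 221800 ± 25650 to 133700 ± 10210 in VAT and from 56400 ± 4245 to 93750 ± 5781 in spleen (interaction log2 -1.46, adjusted p = 0.00274). The spleen call of H2-Eb1 was lost without 3-month spleen replicate 1 (adjusted p = 0.110). The antiviral gene Oasl2 went from 1368 ± 78.6 to 2957 ± 1472 in VAT and from 4849 ± 843 to 1864 ± 255 in spleen (log2 2.38, 0.00485). Trem2 went from 3065 ± 415 to 9139 ± 4801 in VAT and from 202 ± 57.9 to 61.4 ± 27.1 in spleen (log2 3.23, 0.0045). The spleen call of Trem2 was lost with the spleen groups alone (adjusted p = 0.166), in the spleen table (0.112) and without 3-month spleen replicate 1 (0.158). Ly6d, a B cell lineage gene, went from 70.4 ± 34.9 to 632 ± 198 in VAT against 17110 ± 4513 and 12740 ± 3049 in spleen (log2 3.68, 0.00274).

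Further interactions were called for C5ar1 (log2 2.13, adjusted p = 0.00161), with VAT values of 33330 ± 9554 and 55000 ± 5815, for Rsad2 (log2 2.52, 0.00309), with VAT values of 888 ± 189 and 1348 ± 164, and for H2-DMb2 (log2 -2.79, 0.00103). Ndnf, a secreted neuronal factor, went from 759 ± 260.5 to 83.1 ± 41.6 in VAT and from 7.99 ± 9.89 to 69.5 ± 27.3 in spleen (log2 -6.78, 0.00301), with log2 -5.28 without 3-month spleen replicate 1 and -8.28 without replicate 2. The interaction was not called for Maoa (log2 2.26, adjusted p = 0.457), Gdf3 (0.283), Il1b (0.2) or Casp1 (0.746). For Nlrp3 it was log2 1.302 (adjusted p = 0.0661). It was called without 3-month spleen replicate 2 (0.0168), without 24-month spleen replicate 1 (0.0306) and by DESeq2 (0.0107), within a range of 0.0107 to 0.316. The direction turned without 3-month spleen replicate 1 for Casp1 (log2 -0.22).

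**Figure D3:**
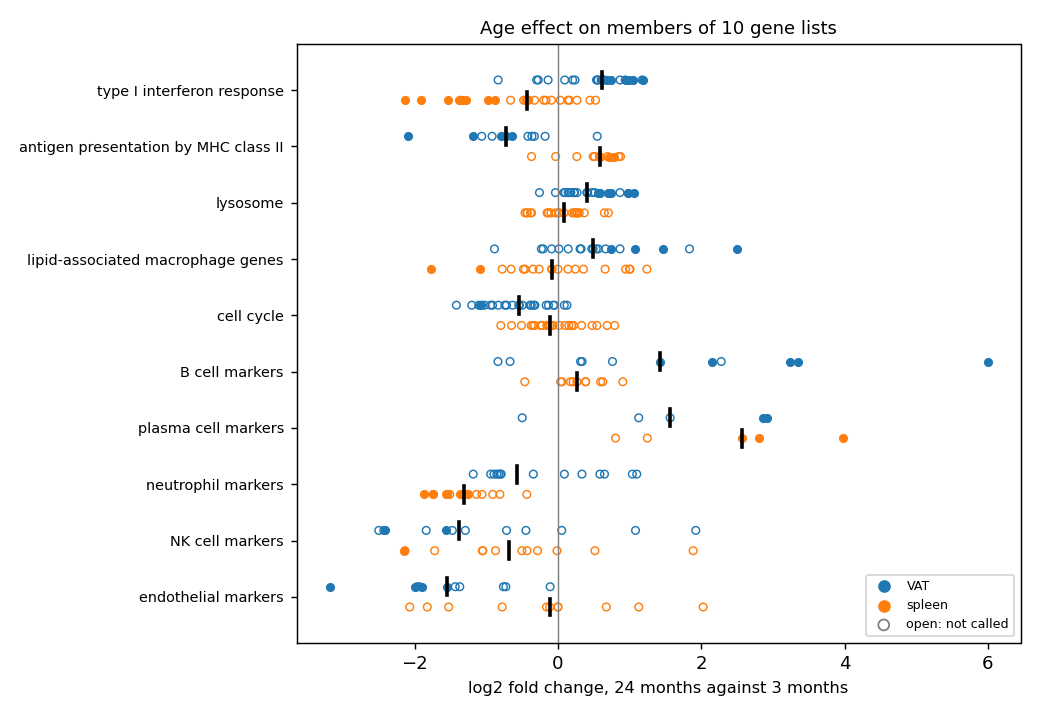
Log2 fold changes with age (24 over 3 months) of the tested members of 10 gene lists in VAT and in spleen. Each point is a gene and the bar is the median of the list. The MHC class II list has a median of -0.7267 in VAT and 0.5853 in spleen.

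For the interaction, 12 of 36 lists were called, 7 upward in VAT relative to spleen and 5 downward, 0 with an estimated correlation, and fry called 6. Interferon genes had a higher age effect in VAT in 11 of 24 called members and a lower one in 0 (14 and 2 adjusted over the list alone, camera adjusted p = 4.99e-11, and adjusted p = 0.14 with an estimated correlation). MHC class II genes had a lower one in 7 of 13 (10 and 0, 4.82e-12, and adjusted p = 0.0892 with an estimated correlation). Lysosome genes gave 3 higher of 23 (3 and 0, 0.00266, and adjusted p = 0.554 with an estimated correlation), lipid-associated macrophage genes 3 of 19 (5 and 1, 0.00783, and adjusted p = 0.683 with an estimated correlation) and immediate early genes 2 of 22 (6 and 0, 0.00314, and adjusted p = 0.498 with an estimated correlation). B cell markers gave 2 higher of 11 (5 and 0, 0.00783, and adjusted p = 0.498 with an estimated correlation), neutrophil markers 1 of 14 (2 and 0, 0.00266, and adjusted p = 0.45 with an estimated correlation) and fibroblast markers 0 of 13 (2 and 1, 0.0455, and adjusted p = 0.498 with an estimated correlation). Downward were endothelial markers with 2 of 11 called (4 and 0, 0.0105, and adjusted p = 0.498 with an estimated correlation), nerve and glia markers with 1 of 5 (2 and 0, 0.0116, and adjusted p = 0.14 with an estimated correlation), dendritic cell markers with 0 of 12 (1 and 1, 0.0116, and adjusted p = 0.14 with an estimated correlation) and cell cycle genes with 0 of 25 (0 and 0, 0.00783, and adjusted p = 0.7 with an estimated correlation). Mean and median differed in sign for the NF-κB list (-0.3114 and 0.0705), the senescence list (-0.1402 and 0.0126) and the mast cell list (0.2879 and -0.0123), none of them called.

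With limma, 375 genes were called for the interaction, 187 with the higher age effect in VAT and 188 with the lower, against 2292 at an unadjusted p under 0.05, and edgeR called 356. The even balance of directions turned either way over the alternatives. The count was 799 with DESeq2, 123 without 3-month VAT replicate 3, 180 without replicate 2 and 206 without replicate 1. It was 212 without 24-month VAT replicate 2, 247 without replicate 3, 135 without 3-month spleen replicate 1, 655 without replicate 2, 224 without 24-month spleen replicate 3 and 249 without replicate 2. Across the age comparisons 108 genes were called in both tissues, 83 in the same direction and 25 in opposite directions, of 1482 called in either.

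Did loss of Nlrp3 change VAT macrophages at 24 months? Nlrp3 itself was the only gene called by limma. Maoa stood at 2381 ± 406 (n = 4) in wild type and 1935 ± 451 (n = 4) in null libraries (log2 -0.32, adjusted p = 0.842). Gdf3 stood at 1417 ± 929.7 and 615 ± 491 (log2 -1.59, 0.79). Il1b stood at 27940 ± 5597 and 34600 ± 5503 (0.8288), and Casp1 at 3405 ± 260.4 and 2763 ± 114 (0.728). Of the catecholamine breakdown list, 2 of 14 members were higher in null libraries, with a median log2 of -0.2271 and 0 called (0 adjusted over the list alone). Camera called the list downward (adjusted p = 0.00871, and adjusted p = 0.358 with an estimated correlation).

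Of the 37 lists tested in VAT, 8 were called for genotype, 5 upward and 3 downward, each with 0 members called over all genes, and neither an estimated correlation nor fry called a list (0 and 0). Mast cell and basophil markers were called upward (5 of 9 adjusted over the list alone, camera adjusted p = 4.74e-07, and adjusted p = 0.26 with an estimated correlation). Neutrophil markers were called upward as well (2 of 9, 0.000503, and adjusted p = 0.26 with an estimated correlation). Plasma cell markers (2 of 5, 0.00857, and adjusted p = 0.295 with an estimated correlation), B cell markers (1 of 9, 0.0305, and adjusted p = 0.398 with an estimated correlation) and T cell markers (0 of 14, 0.0453, and adjusted p = 0.729 with an estimated correlation) were also upward. Resident macrophage genes (0 of 21, 0.0182, and adjusted p = 0.732 with an estimated correlation) and iron genes (0 of 17, 0.0305, and adjusted p = 0.26 with an estimated correlation) were downward. The inflammasome and senescence lists had upward tests with medians of -0.0031 and -0.0055, and the complement list a downward test with a mean of 0.0639, none of them called. Limma called 1 gene, against 797 at an unadjusted p under 0.05, and edgeR called 1. DESeq2 called 33, and without null replicate 4 limma called 3. In simulated data with 200 genes changed DESeq2 made 31 false calls. That number belongs to data with many changed genes, so it does not tell how many of the 33 were false.

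Did loss of Nlrp3 change spleen macrophages at 24 months? Again Nlrp3 was the only gene called by limma, while all 14 neutrophil markers were higher in null libraries, with a median log2 of 0.97. Of these 14 limma called 0 over all genes, fry did not call the list, and its camera call was lost (adjusted p = 0.537 with an estimated correlation). Camp, an antimicrobial peptide of neutrophil granules, stood at 14830 ± 7042 (n = 4) in wild type and 46770 ± 28160 (n = 3) in null libraries (log2 1.604, adjusted p = 0.573), a gene chosen after its values were seen. Maoa stood at 12.6 ± 19.1 and 38.8 ± 6.53 (adjusted p = 0.812), and Gdf3 at 139.6 ± 48.7 and 41.4 ± 57.8 (0.782). Il1b stood at 10590 ± 3606 and 12060 ± 3177 (0.912), turning direction without wild-type replicate 4 (log2 -0.01). Casp1 stood at 2807 ± 472 and 3102 ± 676 (0.948), which turned without null replicate 3 (log2 -0.02).

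Of 36 lists tested in spleen, 16 were called for genotype, 12 upward and 4 downward, each with 0 members called over all genes, and 0 were called with an estimated correlation or by fry. Neutrophil markers were called upward (7 of 14 adjusted over the list alone, camera adjusted p = 7.63e-14, and adjusted p = 0.537 with an estimated correlation). Monocyte markers were upward (3 of 10, 4.13e-06, and adjusted p = 0.109 with an estimated correlation) and erythroid markers upward (0 of 15, 3.11e-05, and adjusted p = 0.537 with an estimated correlation). Pan-macrophage markers were upward (2 of 11, 0.00916, and adjusted p = 0.537 with an estimated correlation). Megakaryocyte markers were downward (1 of 10, 0.000412, and adjusted p = 0.537 with an estimated correlation). B cell markers, with 0 of 11 higher, were downward (0 of 11, 0.00921, and adjusted p = 0.596 with an estimated correlation). MHC class II genes were downward too (0 of 13, 0.00916, and adjusted p = 0.537 with an estimated correlation). The others called upward were glycolysis (0.000823), lysosome (0.00386), cell cycle (0.00916), lipid-associated macrophage (0.0103), iron (0.0171), mast cell (0.0192), complement (0.0376) and immediate early genes (0.0389), and downward eosinophil markers (0.0271), with adjusted p = 0.537 to 0.596 with an estimated correlation. Sign differed between median, mean or test, without a call, for catecholamine synthesis (medians -0.0301), inflammasome (0.0125), resident macrophage (-0.0323), senescence (0.012), cholesterol (-0.0178), NK cell (-0.0596), fibroblast (0.1024) and endothelial genes (-0.2382). The mesothelial list had 1 member measured and was not tested. Limma called 1 gene, against 808 at an unadjusted p under 0.05, edgeR called 1, and DESeq2 called 16. In simulated data with 200 genes changed DESeq2 made 40 false calls, which does not tell how many of the 16 were false.

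Did loss of Nlrp3 turn back the age effect in VAT? In the VAT table, with Nlrp3 left out, 1225 genes were called for age and 0 for genotype, so 0 were called in both and 0 would be for independent lists. Over all genes, 64.56% had a genotype effect of the opposite sign to the age effect, against 65.24% in simulated data with neither an age nor a genotype effect. In those data 0.12 genes were called for age on average. Their share of opposite signs, and their correlation given below, are therefore no reference for data with real age effects, and they decide nothing here. The 24-month wild-type libraries stand in both effects and so tie them together. Across genes, which are not independent replicates, the correlation of the effects was -0.3299, against -0.4615 (SD 0.01276 over 100 draws) in simulated data. The covariance was -0.1315 against -0.1023 (SD 0.003744, range -0.1142 to -0.09225) in those data. It lay below the simulated range, while the correlation was less negative than the simulated one. Each gene was drawn independently of the others in those data. Their range therefore leaves out genes that vary together, and the covariance decides nothing here either. With the wild-type libraries split so that the comparisons shared none, the covariance ranged from -0.05252 to 0.03234 and the correlation from -0.1087 to 0.05597. The share of opposite signs ranged from 49.19% to 58.47% over all genes and from 54.44% to 75.14% among genes called for age. The splits reuse the same libraries, so they are not independent of each other.

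Did genotype act differently in VAT and spleen? Limma called 0 of 12156 genes for the tissue by genotype interaction, against 988 at an unadjusted p under 0.05. Of the other tests edgeR called 1 and DESeq2 69. Without null spleen replicate 3 limma called 11, without replicate 1 it called 2 and without null VAT replicate 4 it called 1. The interaction (VAT minus spleen) had log2 -2.97 for Maoa (adjusted p = 0.47), 1.48 for Gdf3 (0.812), 0.07 for Il1b (0.974), -0.45 for Casp1 (0.663) and -0.01 for Nlrp3 (0.999). Of 35 lists, 7 were called, 6 downward and 1 upward, 0 with an estimated correlation or by fry. Catecholamine breakdown (1 of 13 adjusted over the list alone, camera adjusted p = 0.0212, and adjusted p = 0.489 with an estimated correlation), lysosome (1 of 23, 0.00296, and adjusted p = 0.489 with an estimated correlation), iron (0 of 17, 0.00296, and adjusted p = 0.489 with an estimated correlation) and erythroid genes (0 of 10, 0.00408, and adjusted p = 0.489 with an estimated correlation) were downward. Pan-macrophage markers (1 of 11, 0.023, and adjusted p = 0.489 with an estimated correlation) and lipid-associated macrophage genes (1 of 19, 0.023, and adjusted p = 0.756 with an estimated correlation) were downward too, and B cell markers upward (0 of 9, 0.00477, and adjusted p = 0.489 with an estimated correlation).

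How did macrophages of the tissues differ at 24 months in wild type? The values are those of all sorted cells, and differences in the mix of cells were not tested apart. VAT libraries were higher in 20 of 21 resident macrophage genes, in a list whose call was lost (adjusted p = 0.0729 with an estimated correlation), such as Folr2, a folate receptor, with 22.5 ± 20.2 (n = 4) in spleen and 50820 ± 9392 (n = 4) in VAT. Cd209f, a lectin, stood at 11 ± 8.76 and 129500 ± 51800. They were higher in chemokines, such as Cxcl2, a neutrophil attractant, with 69.5 ± 23.1 and 113600 ± 14770. They were higher in fibroblast genes too, such as Dcn, which encodes decorin, with 4.22 ± 4.39 and 47510 ± 11540. Spleen libraries were higher in neutrophil genes, such as Ngp, with 65190 ± 38520 in spleen and 5.11 ± 5.98 in VAT, and S100a9, with 55150 ± 15390 and 224 ± 121. The B cell gene Cr2 was higher in spleen too, with 4496 ± 1252 and 4.2 ± 6.32. Maoa stood at 11.6 ± 17.5 in spleen and 2549 ± 449 in VAT (log2 8.74, adjusted p = 7.03e-07), with log2 9.65 without spleen replicate 1. Log2 values that moved in the same way were those of Folr2 (11.77, to 12.37 without spleen replicate 2 and 10.82 without 3) and Cd209f (13.74, to 13.03 without spleen replicate 3). Those of Ngp (-13.69, to -14.28) and Cr2 (-10.34, to -11.05) moved without VAT replicate 3. Nlrp3 was higher in VAT, with 441 ± 124 and 3751 ± 684 (log2 3.11, 1.27e-08).

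Gdf15 stood at 33.4 ± 16.1 in spleen and 15520 ± 4871 in VAT, Gdf3 at 128 ± 44.9 and 1512 ± 981 (log2 3.41), and Il1b at 9716 ± 3310 and 29910 ± 6109 (log2 1.67), all higher in VAT. Casp1 was higher in VAT (log2 0.51, adjusted p = 0.0248), a call lost with quantile normalisation (0.106) and without 24-month VAT replicate 2 (0.0561) or 4 (0.0556) or spleen replicate 4 (0.0837), within a range of 0.0114 to 0.106. Tpsb2, a mast cell protease, was at least 667-fold higher in VAT, Dpt, a matrix protein gene of fibroblasts, at least 897-fold and Cidec, a lipid droplet gene of adipocytes, at least 131-fold. Camp was at least 4360-fold lower and Elane, neutrophil elastase, at least 2700-fold lower in VAT.

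Camera called 21 of 36 lists for tissue, 12 upward in VAT and 9 downward, fry called 31, and 8 held with an estimated correlation. Higher in VAT and held were NF-κB cytokines with 20 of 23 higher and 1 lower, immediate early genes with 20 of 22 and 0, complement genes with 17 of 19 and 0, and fibroblast markers with 11 of 13 and 2, each at adjusted p = 0.0396 with an estimated correlation. Lower in VAT and held were neutrophil markers with 13 of 14 and NK cell markers with 11 of 12, at adjusted p = 0.0396 with an estimated correlation. B cell markers with 11 of 11 and megakaryocyte markers with 9 of 10 held at adjusted p = 0.0414 with an estimated correlation. The calls of the others did not hold: catecholamine breakdown, with 9 of 15 higher and 1 lower (camera adjusted p = 0.00237), had adjusted p = 0.0768 with an estimated correlation. Resident macrophage genes with 20 of 21 had adjusted p = 0.0729 with an estimated correlation, and lysosome genes with 22 of 23 had adjusted p = 0.0723 with an estimated correlation. Lipid-associated macrophage genes with 16 of 19 (adjusted p = 0.113 with an estimated correlation), growth differentiation factor genes with 8 of 14 (adjusted p = 0.0604 with an estimated correlation), iron genes with 12 of 17 (adjusted p = 0.241 with an estimated correlation), pan-macrophage markers with 9 of 11 (adjusted p = 0.115 with an estimated correlation) and adipocyte markers with 7 of 10 (adjusted p = 0.0729 with an estimated correlation) were higher in VAT. Erythroid markers with 14 of 15 (adjusted p = 0.107 with an estimated correlation), T cell markers with 12 of 14 (adjusted p = 0.0968 with an estimated correlation), eosinophil markers with 6 of 10 (adjusted p = 0.449 with an estimated correlation), nerve and glia markers with 4 of 5 (adjusted p = 0.0622 with an estimated correlation) and cell cycle genes with 13 of 25 (adjusted p = 0.533 with an estimated correlation) were lower. The counts adjusted over the list alone were the same except for cell cycle genes (14 lower), T cell markers (2 higher) and oxidative phosphorylation genes (3 higher, against 4 over all genes). Medians were above 0 with a downward test for interferon (0.1098) and MHC class II genes (0.1929), and the cholesterol list had a median of -0.099 and a mean of 0.0057, none of them called.

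With limma, 6726 of 13702 genes were called for tissue, 3639 higher and 3087 lower in VAT, against 7523 at an unadjusted p under 0.05, and edgeR called 6316. The balance turned with quantile normalisation (3233 higher and 3806 lower). Over all genes tested the groups did not overlap in 43.3%, where chance would keep groups of 4 and 4 apart in 2.86% of cases. Of the genes named and called, which were chosen for their difference, 56 of 56 did not overlap.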

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

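The tests on B cell genes, on Nlrp3 reads in a null library and on the larger count in the VAT table were chosen only after the result was seen. The comparisons with other splits of the libraries were planned.

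B cell genes in VAT of 24-month mice. Where the sort took cells positive for F4/80 and CD11b, 9 of the 11 B cell markers were higher at 24 months, when Cd79a stood at 715, 538, 747 and 2719 and Ms4a1 at 331, 299, 245 and 1430 in replicates 1 to 4, so that replicate 4 carried much of the means. A single library was not the source, since Cd79a, Cd79b, Ms4a1, Blk, Jchain and Mzb1 were all 6 still called without replicate 4, the highest in Cd79a. B cells like those in the spleen libraries, which bring Fcer2a and Cr2, were argued against, as these genes summed to 7.02% of the level that Cd79a would bring with them, although Ms4a1 (245 to 1430, against 437 to 2210 at that level), Cd22 (134 to 1640, against 169 to 853) and Blk (12.6 to 190, against 54.1 to 274) lay nearer to it. A lower share of macrophages would raise the NK, T and endothelial lists only if those cells otherwise kept their numbers. The lowest median log2 change of these lists was -1.5421, which therefore does not decide on a lower share, and that explanation stays open. B cells of another kind among the sorted cells stay open as a candidate source. Sorting with an antibody to Ms4a1 to remove B cells would test that hypothesis for the B cell genes. It was not taken to cover the plasma cell genes Jchain and Mzb1, whose source was not tested. An effect of age itself stays open as well and was not tested apart from these cells.

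Nlrp3 reads in 1 null VAT library. Replicate 4 held 200.4 normalised counts of Nlrp3, where the other null VAT libraries held 6.15 to 10.51. RNA of wild-type spleen in that library was argued against, since the share of 46% that it would need would bring S100a8 far above the level seen, which was 1.63% of that level. RNA of wild-type VAT stays open, as a share of 5.41% would be enough and, with 1 gene called between these genotypes in VAT, no value here decides it. Remaining transcript of the altered gene was not tested.

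More genes called for age in VAT in the VAT table. The count was 740 in the wild-type table and 1225 in the VAT table. Replaced entries of the VAT table were argued against, since 1227 genes were called with the differing entries set back to the reads of the wild-type table. The spread of the spleen libraries in the shared fit of the wild-type table stays open as a source. With the VAT libraries of the wild-type table alone 1159 genes were called. Over all genes tested the median residual SD was 0.342 in VAT and 0.385 in spleen. Among the 481 genes gained it was 0.294 in VAT and 0.556 in spleen, and 424 of them spread more in spleen. Picking genes by this refit favours such a difference. No biological explanation was tested.

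Other splits of the same libraries. For age in VAT, the real split called the most genes (740, 1 of 35 splits as high). That is the lowest share that 35 splits can give, so it speaks against chance but cannot exclude it. The highest other split called 194 and put 24-month replicate 1 with the young libraries. The 18 lists lay above the other splits (1 of 35, highest other 15, median of the others 9). As 0 of them held with an estimated correlation, while fry called 11, chance was not taken as excluded for the lists. For tissue the 6726 genes also had the lowest share that 35 splits can give (1 of 35, highest other 1). This speaks against chance in the same way, without excluding it. For the 21 lists the count of splits (3 of 35, highest other 21) does not decide it, because the other splits as high exchanged 1 library per tissue and so kept part of the tissue difference. For genotype the gene called was Nlrp3 itself in both tissues, called under every alternative, and a count of splits that ignores which gene is called says nothing on it. In VAT chance cannot be excluded as the source of a count of 1 gene (7 of 35, highest other 131, a split that points to a structure among these libraries) or the 8 lists (24 of 35, highest other 14). In spleen it cannot be excluded as the source of a count of 1 gene (3 of 35, highest other 11). The 16 lists there were 1 above the highest other split (1 of 35, highest other 15) but fell to 10 with the replicate block and to 0 with an estimated correlation or fry, so chance was not taken as excluded. For tissue by genotype it cannot be excluded for the 7 lists (49 of 100, highest other 15), and with 0 genes called the count of splits was fixed at 100 of 100 and decides nothing (highest other 10). Age in spleen and tissue by age hold a group of 2 libraries and were not compared with other splits.

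Single libraries far from their group. Of 265 distinct pairs of a named gene and a group of 4 libraries, 35 (13.2%) had a library whose gap to the others passed the Dixon limit, 31 on the high side. Chance passes this limit in about 1 in 20 groups of normally distributed values. The counts used here were not logged and stop at 1, so that share does not apply. Where all other libraries stood at 1, any higher value passed, as for Gp5 (1.138), Tmem132b (1.874) and Fcnb (3.799). The genes were also partly chosen for large changes. In 24-month VAT replicate 4, with 11 of them, the normalised counts were 795 for Faim3, 2719 for Cd79a, 16320 for Trem2, 52350 for Akr1a1, 1309 for Ccnb2, 27.55 for Cuzd1, 3.799 for Fcnb, 3.799 for Mpzl2 and 39.89 for Angptl7 on the high side, and 26290 for Cbr2 and 10.45 for Tubb1 on the low side. In 24-month VAT replicate 3 they were 251.5 for Hbb-b2 and Hbb-bt (1 measurement), 13.68 for Cr2 and 47.35 for Fcer2a on the high side, and 167.3 for Klrk1 and 1 for Art3 on the low side. Replicate 1 held 84.18 for Ltf and 1.138 for Gp5, replicate 2 held 82.67 for Tubb3, and null VAT replicate 4 held 200.4 for Nlrp3. In 24-month spleen replicate 1 there were 37.54 for Maoa in the wild-type table and 40.82 for Maoa in the spleen table, 881.7 for Cd93, 1342 for Epx, 2052 for Bnip3, 185.9 for Mpzl2, 34.79 for Lonrf3 and 8.24 for Amy2a5. In spleen replicate 2 there were 354.3 for Retnla, 22.49 for Cd209g, 18.74 for Atp8b5, 11.25 for Angpt2 and 1.874 for Tmem132b. Spleen replicate 3 held 18.68 for Tmem204 and 12.45 for Wt1, and replicate 4 held 4412 for Tcf4.

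Age effects that differed between the tissues by the interaction test were found for 61 named genes, given as the log2 effect in VAT minus that in spleen. Many of these genes were named for a called interaction, and some were chosen after their values were seen. Their number therefore follows from the choice of genes and is no result in itself. The effect was higher in VAT for Cd79a (2.98), Ly6d (3.68), Fbln7 (4.81), Nr1h4 (4.68), Cyp1b1 (4.59), Pde7b (3.97), Pla1a (3.40), Trem2 (3.23), Gdf15 (2.42), C3 (2.07), C5ar1 (2.13), Csf3r (2.02), Acsl1 (1.73), Txnip (1.74), Cd3g (1.69), Atf3 (1.62), Cd93 (1.56), Bnip3 (1.41), Cd63 (1.33), Ctsd (1.20), Zfp36 (1.09), Lamp2 (0.93) and Emb (0.79). Among interferon-induced genes it was higher for Rsad2 (2.52), Oasl2 (2.38), Ifit3 (1.93), Usp18 (1.15) and Isg15 (1.15). It was lower in VAT for the MHC class II genes H2-DMb2 (-2.79), H2-DMa (-1.68), H2-Eb1 (-1.46) and H2-Aa (-1.36), for Sdc1 (-3.31), Icam1 (-0.93), Ccr2 (-1.30), Cd4 (-1.93), Klrk1 (-2.41), Ear2 (-2.10), Pecam1 (-1.43), Esam (-3.12), Aldh1a1 (-3.64), Napsa (-1.63), Slc3a2 (-1.55), Plbd1 (-1.43), Lyz1 (-1.32) and Lsp1 (-1.16). Krt18 (-4.50), with no library at the floor, was lower too, with -2.53 without 3-month spleen replicate 1 and -6.47 without replicate 2. Larger differences in genes with at least 1 library at the floor, whose fitted values depend on the pseudocount, were Tspan7 (-7.13), Pik3r3 (-6.80), Ndnf (-6.78), Art3 (-6.69), Mpzl2 (-6.66), Angptl7 (-6.41), Tubb3 (-6.30), Stap2 (-6.21), Trabd2b (-6.18), Chst1 (-5.97), Akr1c18 (-5.43), Hhip (-4.53), Tenm2 (-4.45) and Mmp23 (-4.36). The pseudocount matters in the same way for Fbln7, Nr1h4 and Cyp1b1. Single libraries moved several of these differences as well. Without 3-month spleen replicate 1 and without replicate 2, they were -8.36 and -5.01 for Art3 and -7.98 and -4.44 for Stap2. In the same order they were 5.65 and 3.53 for Cyp1b1 and 2.50 and 4.30 for Pla1a. Without 3-month VAT replicate 1 and without replicate 3, they were -7.79 and -5.88 for Mpzl2 and 3.98 and 5.60 for Fbln7. Over all alternatives, 14 of 44 genes named and called in this comparison stayed called under every one and 30 were lost under at least 1.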

How the results depend on the processing

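The DESeq2 tests and the entries set back to the wild-type table were chosen only after the result was seen. The other alternatives were planned. Over the genes named, 4342 values under an alternative kept direction and side of the threshold, 586 lost the call, 11 gained it and 21 changed sign. Lost calls came with single libraries left out more than with other settings: leaving out each library in turn gave 216 to 794 genes for age in VAT (740 as reported), 180 to 948 in spleen (850), 123 to 655 for tissue by age (375), 1 to 3 for genotype in VAT (1) and 0 to 11 for tissue by genotype (0), where fewer libraries also mean a weaker test and a spleen group left with 1 library was assumed to vary like the other groups. With only the groups compared, age gave 1159 genes in VAT (678 of them among the 740) and 546 in spleen (420 among the 850). In the VAT table age in VAT gave 1225 (666 shared), and 1227 with the differing entries set back (668 shared). DESeq2 called 1172 genes for age in VAT, 1435 in spleen, 799 for tissue by age and 69 for tissue by genotype. For genotype it called 33 in VAT and 16 in spleen. In simulated data with 200 genes changed DESeq2 made 25 to 42 false calls against 3 to 8 with limma. These numbers do not tell how many calls in the real data were false. Robust limma and edgeR each called 1 gene for tissue by genotype. With the replicate number as a block, genotype called 2 genes in VAT and 5 in spleen, and the lists called were 10 for genotype in spleen and 12 for tissue by genotype. The numbers do not pair libraries by correlation (2 of 16 same-number pairs above 0.1, range -0.146 to 0.24). Lists called with an estimated correlation were 0 for both age effects, both genotype effects and both interactions and 8 for tissue, and fry called 11 for age in VAT, 5 in spleen, 6 for tissue by age and 0 for genotype in VAT, genotype in spleen and tissue by genotype. The correlation of age and genotype effects averaged -0.02347 with the wild-type libraries split, which removes the shared libraries by construction. Signs changed only in values never called. With libraries left out in turn, Maoa (-2.99 to 0.96) and Casp1 (-0.0263 to 0.87) for age in spleen, Il1b (-0.0089 to 0.40, and -0.0089 with the replicate block) and Casp1 (-0.0207 to 0.30) for genotype in spleen, Casp1 (-0.22 to 0.68) for tissue by age, and Il1b (-0.10 to 0.31) and Nlrp3 (-1.11 to 0.50) for tissue by genotype changed sign, Nlrp3 also with a pseudocount of 0.5 (0.27), edgeR (2.77) and DESeq2 (2.82), where it stands near the floor in the null libraries. Where no cause is given, the cause was not tested. Another table with both groups exists for the age effects only, and for tissue by age all groups of the table are in the comparison, so these alternatives could not be run elsewhere. At 24.1 to 37.5 M (mega) reads, genes under about 2.33 to 3.85 normalised counts were not separable from 0.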

Other observations

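The genes in this part were chosen only after the result was seen, from genes with small adjusted p in the age comparisons that the rule did not name. C130026I21Rik (chromosome 1, 84992690 to 85270566 in mm10), a clone-named gene and so left out of the largest changes by the rule, had the smallest adjusted p in VAT. It rose from 15.1 ± 9.97 (n = 3) at 3 months to 981 ± 352 (n = 4) at 24 months in VAT (log2 6.06, adjusted p = 3.67e-06) and from 68.5 ± 27.8 (n = 2) to 2104 ± 537 (n = 4) in spleen (log2 4.95, adjusted p = 0.000103). The labels do not say whether the young and old mice came from the same colony, so this is a difference between the age groups that was not shown to come from age. The age effect was not called different between the tissues (interaction log2 1.11, adjusted p = 0.404). Null libraries stood at 963 ± 299 in VAT (n = 4, against 919 ± 336 in wild type, adjusted p = 0.989) and 1513 ± 329 in spleen (n = 3, against 2293 ± 589, adjusted p = 0.793).

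Some genes of myeloid cells fell with age in VAT. Lyz1, a lysozyme, fell from 132800 ± 37750 (n = 3) to 33202 ± 7596 (n = 4, log2 -1.99, adjusted p = 0.000147), and Napsa, an aspartic protease, from 6155 ± 378 to 2194 ± 351 (log2 -1.50, 3.12e-05). Plbd1, a phospholipase B-like gene, fell from 16304 ± 1356 to 5894 ± 1080 (log2 -1.48, 9.51e-05), and Lsp1, an actin-binding protein of leukocytes, from 41802 ± 4967 to 14015 ± 2887 (log2 -1.60, 0.000122). In spleen Slc3a2, a chain of amino acid transporters, rose from 2765 ± 58.6 (n = 2) to 7154 ± 832 (n = 4, log2 1.36, adjusted p = 0.000103), and Emb, the adhesion gene embigin, fell from 11262 ± 997 to 4109 ± 438 (log2 -1.46, 0.000103). Each of these calls held under every alternative tried.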
